A study of Mus musculus with 2 samples.

How the data were processed

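Whole brain of B6NCrl mouse embryos at day 14.5 was profiled by poly(A) RNA-seq in 2 libraries of a single group, numbered by the labels' biological replicate numbers, which do not say whether they came from separate animals. The aligner, the counter's version, the library kit, the read layout and the strand setting are not given in the sources used here.

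Genes and transcripts were quantified by the authors from alignments to the transcriptome on mm10 with GENCODE M4, per the deposited README files. The column names are those that RSEM writes, per the file headers. Estimated counts (the expected count per gene and its posterior mean) are the authors' values, unnormalised, in which reads shared between transcripts are split by the estimator. TPM was computed by the authors over every row, per the file headers, so that phiX174 takes 52.9% of it in replicate 1 and 56.4% in replicate 2. The percent of a gene's TPM held by each transcript is also the authors' deposited value. Annotated length exceeded effective length by 35 bases in 99.95% of rows.

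Each gene table has 69691 rows: 43346 mouse genes, 26248 rows whose identifier is a number, 96 ERCC rows and phiX174. Only mouse genes entered library sizes and tests. Gene identifiers were matched without their version to GENCODE M21, which uses the same assembly as mm10, GRCm38, and 42462 of the 43346 matched a symbol. The 884 others held 1048 and 63 counts. Gene types and coordinates are those of M21. Because the estimator splits reads among copies, genes with paralogs or pseudogenes and genes overlapping others are uncertain.

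The lists, gene pairs, tests and rule for named genes below were fixed before the data were examined. A gene was called detected at a TPM of at least 1 in both libraries. The 39 lists, of 408 distinct genes, cover progenitors and cell cycle, neuron classes, glia, vessels and blood, brain regions and Hox genes. They also cover signalling pathways, axon guidance and migration, and neighbouring tissues (meninges, muscle, cartilage, epidermis, sensory ganglion, pituitary, eye and liver). Others hold imprinted, sex-linked, pluripotency and immediate early genes, mitochondrially encoded messenger RNAs and RNAs taken to lack a poly(A) tail. Each list's median log2(mean TPM + 1) was placed among 10000 random lists of protein-coding genes detected in both libraries. Pairs were compared as log2 ratios of TPM + 0.1. The Hox relation used a two-sided permutation test of Spearman's rho on log2(mean TPM + 0.1), and an exact permutation test in clusters of 9 genes. Ratios between libraries used counts scaled by TMM with 0.5 added, over genes of at least 100 summed counts. A list's shift was its median ratio among 10000 random lists matched in 20 bins of mean expression. Estimated counts were rounded to whole numbers for edgeR, whose common dispersion of both libraries as a single group (TMM, filterByExpr) gave the biological coefficient of variation. A dominant transcript held at least 80% of a gene of at least 5 TPM in both libraries. As there is a single group, no comparison between groups and no paired analysis arises.

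Named genes are the 20 protein-coding genes of highest mean TPM, the 4 highest and the lowest of each list, both members of each pair, Hox genes of at least 1 TPM in both libraries and the highest of each paralog group, the 10 genes with the largest ratio each way among those of at least 100 summed counts, the 8 highest of 22 isoform genes and every sex-linked gene, with some left out in rank order for length. Genes of at least 20 summed counts with over 90% in a single library, the most abundant genes in both libraries, and the length-matched random lists (20 bins), with their Benjamini-Hochberg adjustment, were chosen after the data had been examined. So were the tests on shared sequence windows, but that over all 53 genes was set before its own result was seen.

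Alternatives were other TPM thresholds, posterior means, CPM, other pseudocounts, DESeq2 size factors, total-count scaling, other filters on low counts, other transcript shares and each library alone. TPM rescaled to mouse genes, at least 3 counts in both libraries, at least 1 count in both and at least 20 counts in both were added after the data had been examined.

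The scripts were tested on simulated counts with the files' means and library sizes, a biological coefficient of variation of 0.4 and 200 genes changed 4-fold between the libraries. The estimate was 0.419 over 151 genes at the files' depth and 0.396 over 5713 genes at 20 times that depth. Without the filter on low counts it was 0.519 over 7152 genes and 0.428 over 8776 genes. At the files' depth 87.5% of 8 changed genes of at least 100 counts were found 2-fold apart, as were 15.8% of 19 unchanged ones. At that depth 4% of random lists of 8 genes, drawn from 933 genes, fell outside the central 95%.

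Shares carry 95% Wilson intervals, and a count of 0 was taken to allow 3 counts. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Signal tracks and alignments were not analysed here.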

Results

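Poly(A)-selected RNA was sequenced from whole mouse brain at embryonic day 14.5, when cortical neurogenesis is under way, in 2 libraries that the labels number as biological replicates 1 and 2 of the same group. The total estimated count was 157580 in replicate 1 and 151598 in replicate 2. The row of the bacteriophage phiX174 genome, a common sequencing control, held 83.9% of it in replicate 1 (95% Wilson interval 83.7 to 84.1) and 84.0% in replicate 2 (83.8 to 84.2). Mouse genes received 25316 and 24148 counts, and the 96 rows of the ERCC spike-in RNAs received 0 counts in both libraries. At this depth 1 count on 1000 bases was worth 21.4 TPM in replicate 1 and 23.7 TPM in replicate 2, so that a gene listed at 0 can still be expressed. A count of 0 allowed up to 119 CPM of the mouse counts in replicate 1 and 124 CPM in replicate 2. Intervals and such limits cover counting error only. The labels name the same donor for both libraries and describe the tissue both as from an individual mouse and as pooled from males and females, so the spread between the libraries may be partly technical.

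Map1b, which encodes a microtubule-associated protein of growing axons, had 118 and 138 counts in replicates 1 and 2 (245 TPM ± 44.5, SD, n = 2; chromosome 13, 99421446 to 99516540, GRCm38). Tuba1a, the main alpha-tubulin of migrating neurons, had 123 and 66.5 counts (3057 TPM ± 2137), and Tubb5, a beta-tubulin of dividing progenitors and neurons, had 40.6 and 71 counts (779 TPM ± 5.92). Actb, cytoplasmic actin, had 56.0 and 135 counts (1242 TPM ± 858), and Cd24a, a surface glycoprotein of young neurons, had 29 and 32 counts (388 TPM ± 54.6). Nrep, a neuronal regeneration protein, had 29 and 104 counts, and the RNA-binding proteins Hnrnpa2b1 and Hnrnph1 had 29 and 31 and 25 and 26 counts. Map1b, Tubb5, Cd24a, Nrep, Hnrnpa2b1 and Hnrnph1 were chosen after their values were seen, among those with the most counts in the library where each had fewer.

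Of the 20 protein-coding genes with the highest mean TPM, mt-Co2, mt-Atp6, mt-Co1, mt-Cytb, mt-Atp8, mt-Nd4l, mt-Nd1 and mt-Nd4 are encoded by mitochondrial DNA. Eef1a1, a translation elongation factor, ranked at 8365 TPM ± 9167 (SD, n = 2), Calm1, a calcium sensor, at 2241 TPM ± 2989 and Rpl37a, a ribosomal protein, at 1942 TPM ± 2633. Tpt1, Ptma and Actg1 followed at 1584 TPM ± 736, 1331 TPM ± 995 and 1097 TPM ± 1302. The chaperone Hsp90ab1 had 1052 TPM ± 1063 and the adult-type alpha-globin gene Hba-a2 had 932 TPM ± 840. For Eef1a1, Calm1, Rpl37a, Actg1 and Hsp90ab1 the SD exceeded the mean. Malat1, a nuclear noncoding RNA, had 136 and 104 counts.

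A total of 8784 mouse genes had a count in at least 1 library, 6080 in replicate 1 and 6142 in replicate 2. Both libraries listed 3435 genes at 1 TPM or more, of which 3323 were protein-coding. With counts above 0 the shared genes numbered 3438, against 862 for independent lists of these sizes over all mouse genes. Among protein-coding genes alone 3325 were shared, against 1457. Only 92 genes had at least 10 counts in both libraries.

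By share of members at 1 TPM or more in both libraries, the leading lists were the mitochondrially encoded (11 of 13), pan-neuronal (11 of 14), radial glia (8 of 12), diencephalic (4 of 6) and imprinted (13 of 20) genes. The pan-neuronal list had 11 of 14 members at 1 TPM or more in both libraries, and all 14 had a count in at least 1. Its leading members were Stmn2, a microtubule regulator of growing neurites, with 57 and 11 counts (524 TPM ± 560, SD, n = 2), the neuronal tubulin Tubb3 with 55 and 4, the dendritic protein Map2 with 21 and 34 (234 TPM ± 26.7) and doublecortin, Dcx, with 22 and 44 (178 TPM ± 105). Radial glia, the neural stem cells of the ventricular wall, were represented by 8 of 12 members in both libraries, led by Vim with 26 and 13 counts, Slc1a3 with 3 and 8, Sox2 with 2 and 14 and Fabp7 with 2 and 3. Cell cycle genes had 7 of 12, among them the cyclin Ccnd2 with 10 and 21 counts, Cdk1 with 2 and 1 and Pcna with 0.05 and 3.37. The imprinted list had 13 of 20 members in both libraries, among them Nnat with 50 and 11 counts, Gnas with 16.4 and 18, Meg3 with 11 and 54.0 and the growth regulator Grb10 with 19 and 10.

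Against 10000 random lists of nuclear protein-coding genes matched on length, 6 of the 37 lists compared had as many members with a count in both libraries in under 2.5% of the random lists. These were the pan-neuronal list (11 members against a random mean of 2.58, 0.00% of lists), the imprinted list (11 protein-coding members against 3.59, 0.00%), radial glia (8 against 2.79, 0.12%), cell cycle (7 against 2.46, 0.21%), diencephalon (4 against 1.36, 1.83%) and glutamatergic genes (6 against 2.78, 2.44%). After Benjamini-Hochberg adjustment over the 37 lists the first 4 stayed under 0.05 (0.00185, 0.00185, 0.0160 and 0.0203), while diencephalon (0.136) and glutamatergic genes (0.151) did not. The 7 cell cycle members include Pcna, which had only 0.05 of an estimated count in replicate 1, and at 5 TPM 6 members remained. The comparison was not repeated without Pcna, so the cell cycle result is uncertain. With at least 3 counts in both libraries these 6 lists had 8, 8, 4, 2, 1 and 2 members. Here the imprinted list was counted over all 20 members, noncoding ones such as Meg3 included, not over the 17 protein-coding ones compared above. The comparison describes these libraries and is not a test over samples. Its adjusted p-values come from drawing genes as if list members were independent, which they need not be. The pan-neuronal list also had a median of 5.41 on the log2(mean TPM + 1) scale, at the 95.8th percentile of random lists drawn from protein-coding genes detected in both libraries, and the erythroid list had 4.65, at the 57.6th. The mitochondrially encoded list had 11.61, at the 100th. As these random lists hold detected genes only, a list with undetected members falls low among them whatever the level of its other members, and low percentiles are not read as low expression.

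**Figure D1:**
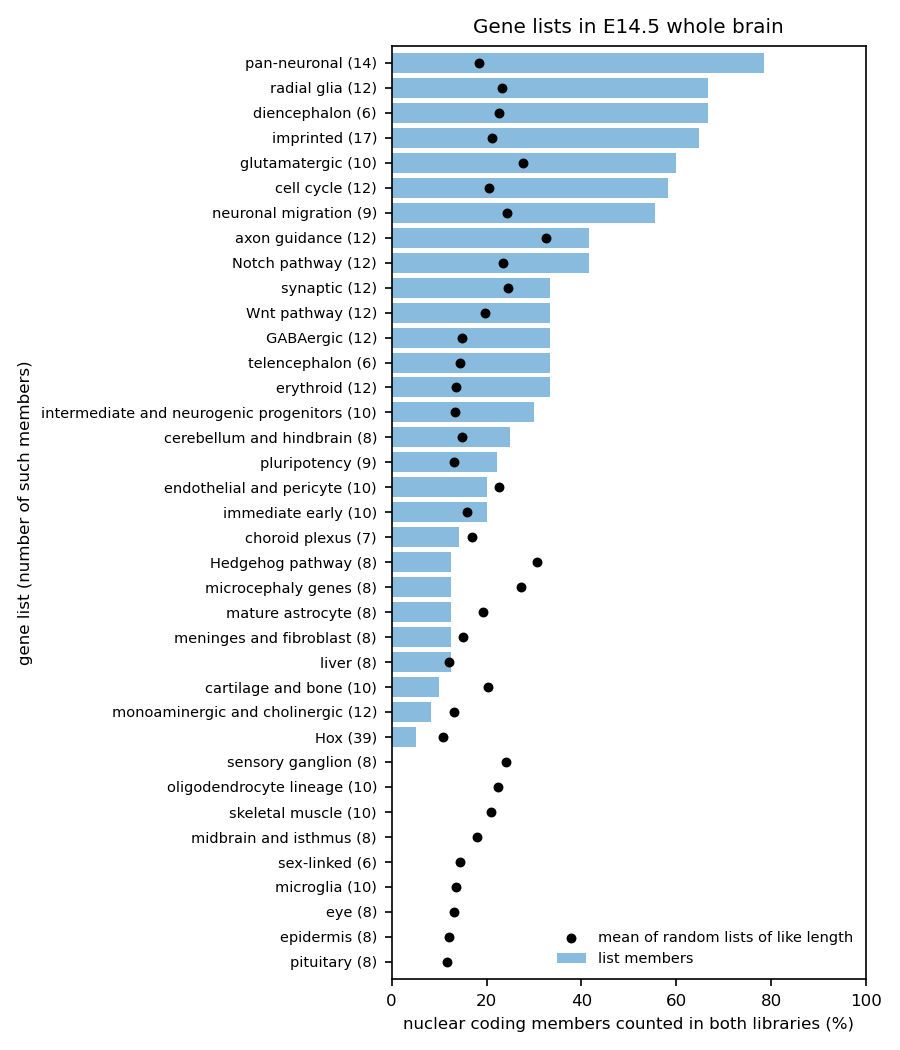
Share of the nuclear protein-coding members of each gene list (percent, horizontal axis) that had a count in both E14.5 whole brain libraries; bars are the lists, with the number of such members in parentheses, and points are the mean of 10000 random lists of like gene length. The pan-neuronal bar stands for 11 of 14 members against a random mean of 2.58, and the microglia bar for 0 of 10 against 1.36.

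Among neuron classes, glutamatergic genes had 6 of 10 members in both libraries and all 10 in at least 1. They were led by Neurod6 with 4 and 3 counts, the vesicular glutamate transporter Slc17a6 with 0 and 11, Neurod1 with 4 and 2 and Bcl11b, a factor of deep-layer projection neurons, with 2 and 5. GABAergic genes had 4 of 12, with Dlx1 at 1 and 6 counts, the GABA-synthesising enzyme Gad1 at 2 and 2 and Arx at 4 and 2. Monoaminergic and cholinergic genes had 1 of 12, Nr4a2, with 2 and 1 counts. Synaptic genes had 4 of 12, led by the scaffold Dlg4 with 3 and 4 counts and the glutamate receptor subunit Gria2 with 13 and 5. Intermediate and neurogenic progenitor genes had 3 of 10, led by Eomes, the marker of intermediate progenitors, with 19 and 5 counts, and 13.5% of random lists of like length had as many. Microcephaly genes had 1 of 8, Cdk5rap2, with 1 and 3 counts.

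Genes that guide and place neurons all had a count in at least 1 library. All 12 axon guidance genes did, as in 0.16% of random lists of like length (not adjusted). All 12 had a count in replicate 2, but only 5 in replicate 1. The 5 at 1 TPM or more in both libraries lay near the random mean of 3.90 (34.2% of random lists had as many). Among them were the receptor Robo2 with 11 and 4 counts and the guidance cue Ntn1 with 4 and 5, while Slit2 had 0 and 8 and Efnb2 0 and 24. All 9 neuronal migration genes had a count (0.08% of random lists, not adjusted) and 5 were in both libraries (3.33% had as many, Benjamini-Hochberg adjusted p 0.177 over the 37 lists). The 5 included Reln, the signal released by Cajal-Retzius cells, with 8 and 7 counts (116 TPM ± 4.73, SD, n = 2), and its receptor Lrp8 with 3 and 6. Notch pathway genes had 5 of 12 members in both libraries (11.1% of random lists had as many), led by Rbpj, the transcription factor of the pathway, with 4 and 13 counts. Wnt pathway genes had 4 of 12 (18.7%), led by Ctnnb1, beta-catenin, with 50 and 3 counts. Hedgehog pathway genes had 1 of 8 (95.3%), Gli3, with 1 and 2 counts.

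Regional transcription factors had few counts each. Telencephalic genes had 2 of 6 members in both libraries, Lhx2 with 8 and 3 counts and Foxg1 with 4 and 2. Diencephalic genes had 4 of 6, Tcf7l2 with 5 and 3 counts, Gbx2 with 2 and 2, Lhx9 with 1 and 3 and Otp with 1 and 1. Cerebellar and hindbrain genes had 2 of 8, Lhx1 with 7 and 5 counts and Zic1 with 3 and 5. The midbrain and isthmus list had 0 of 8 in both libraries, with En2 at 0 and 1 count and Lmx1b at 1 and 0, and 19.1% of random lists of like length had as few.

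For no glial, vascular or neighbouring-tissue list did the small number of members with a count pass 0.05 against random lists of like length after Benjamini-Hochberg adjustment over the 37 lists (smallest adjusted p 0.258). The microglia, epidermis, pituitary and eye lists had 0 members with a count, the lowest number possible, and still did not pass. For these lists the comparison could thus not show a shortage, and it does not speak for or against the presence of these cells. The microglia list had 0 counts over its 10 members in both libraries, which allows up to 0.0119% of mouse counts in replicate 1 and 0.0124% in replicate 2. Of 10000 random lists, 1.05% had as few members with a count in either library. Oligodendrocyte lineage genes had 0 of 10 in both libraries, with Plp1 at 6 and 0 counts (5.74% of random lists had as few in both, and 21.1% as few in either). Mature astrocyte genes had 1 of 8, Slc1a2, with 2 and 12, against a random mean of 1.54. Endothelial and pericyte genes had 2 of 10, Pdgfrb with 1 and 2 counts and Cdh5 with 1 and 1, against a random mean of 2.27, and 6 in at least 1 library against 4.97. Choroid plexus genes had 1 of 7, Ttr, a carrier secreted by this epithelium, with 3 and 5 counts, against 1.19, and 4 in at least 1 library against 2.80. Erythroid genes had 4 of 12 members in both libraries (5.94% of random lists had as many), 9 in at least 1 (0.22%), and 62.0 and 36 counts in all, led by the globin genes Hba-a2 with 37.0 and 7.40 counts (932 TPM ± 840, SD, n = 2), Hbb-bs with 508 TPM ± 231 and Hba-a1 with 0 and 12.6 counts. Hba-a1 and Hba-a2 are near-identical, and their shares are uncertain.

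Markers of neighbouring tissues had few counts. The epidermis, pituitary and eye lists, each of 8 genes, had 0 counts in both libraries, and 3.48%, 6.25% and 3.22% of random lists had as few members with a count in either. Skeletal muscle genes had 0 of 10 members in both libraries, with Ttn at 0 and 1 count, and 2.12% of random lists had as few in either. Cartilage and bone genes had 1 of 10, Col2a1, with 1 and 4 counts. In both libraries 35.1% of random lists had as few members, and in either 1.67%. Sensory ganglion genes had 0 of 8 in both, with Pou4f1 at 2 and 0 counts, and 13.7% had as few in either. Meninges and fibroblast genes had 1 of 8, Col3a1, with 3 and 1 counts, and 4 in at least 1 library against a random mean of 3.05. Liver genes had 1 of 8, Afp, alpha-fetoprotein, with 5 and 2 counts, and 4 in at least 1 library against 2.70.

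Early and later partners of 14 developmentally switched gene pairs were compared within each library. The early NMDA receptor subunit Grin2b exceeded the later Grin2a in both, with 2 and 2 counts against 0 and 0, and the early glycolytic enzyme gene Eno1 exceeded Eno2 in both on the TPM scale, with 1.67 and 4 counts against 3 and 0. The later partner was higher in both libraries for Gabra1 over Gabra2 (2 and 1 counts against 0 and 0), for Hbb-bt over the embryonic globin Hbb-y (5.18 and 1.99 against 3 and 1) and for Dlg4 over Dlg3 (3 and 4 against 0 and 4). The other 9 pairs went apart between the libraries or had 0 counts for both genes in at least 1 of them. Among these, Scn3a and Scn1a had 10 and 2 summed counts, Slc17a6 and Slc17a7 11 and 1, Ptbp1 and Ptbp2 2 and 23, Tubb2b and Tubb4a 9.51 and 9, Camk2b and Camk2a 3 and 5, and Actl6a and Actl6b 3.88 and 1. Slc12a2 over Slc12a5 and Lmnb1 over Lmna rested on 1 count each, and Glra2 and Glra1 were both listed at 0. The early partner was thus higher in both libraries in 2 of 14 pairs, against 7 in replicate 2 alone, 4 in replicate 1 alone and 5 in both with posterior mean TPM. On CPM it was also 2, but another pair: Eno1 fell below Eno2 in replicate 1, and Scn3a exceeded Scn1a in both (3 and 7 counts against 2 and 0). The later partner was higher in 3 pairs on either scale, with Ptbp2 over Ptbp1 (9 and 14 counts against 2 and 0) in place of Dlg4, which was level with Dlg3 in replicate 2 on CPM. With 2 libraries the smallest p an exact test could give for any pair is 0.5, so that no pair was tested.

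Hox genes, which pattern the hindbrain and spinal cord, had few counts. Of 39 genes, 7 had a count, against a random mean of 12.1, with 2 counts in replicate 1 and 9 in replicate 2. Of random lists of like length 4.76% had as few (Benjamini-Hochberg adjusted p 0.294 over the 37 lists). Hoxb5 and Hoxb8 had 1 count in each library and were the only members at 1 TPM or more in both. Hoxb2 and Hoxb3 had 0 and 2 counts each, and Hoxb6, Hoxc6 and Hoxd11 had 0 and 1 each, so that the highest members of paralog groups 2, 3, 5, 6, 8 and 11 were Hoxb2, Hoxb3, Hoxb5, Hoxc6, Hoxb8 and Hoxd11 and all other groups were listed at 0. Level did not follow paralog number detectably, with a Spearman rho of -0.155 across the 39 genes (two-sided permutation test with 100000 resamples, p = 0.348, Benjamini-Hochberg adjusted 0.667 over 4 tests). Within the b cluster rho was -0.265 over 10 genes (permutation p = 0.462), and in the c and d clusters of 9 genes it was -0.274 and 0.274, each resting on 1 gene (exact permutation p = 0.667). The a cluster of 11 genes had 0 counts. Genes are not independent replicates.

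Xist, the noncoding RNA expressed from the inactive X chromosome of females, had 17 and 74 counts (114 TPM ± 133, SD, n = 2). The Y-linked genes Ddx3y and Kdm5d had 0 and 1 count each, and Eif2s3y, Uty, Zfy1 and Sry were listed at 0. Of the 7 sex-linked genes, 1 was at 1 TPM or more in both libraries. The pluripotency list had 2 of 9 members in both libraries, Nanog with 110 and 1 counts and Lin28b with 2 and 2. Immediate early genes had 2 of 10, Dusp1 with 1 and 2 counts and Jun with 1 and 1.

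The libraries differed strongly in their abundant genes. Lars2, the mitochondrial leucyl-tRNA synthetase, was higher in replicate 2 by 3.75 on the log2 scale (25.0 and 353 counts), as were Nrep by 1.78 and Actb by 1.21. Eef1a1 had a log2 ratio of replicate 2 over replicate 1 of -2.96 (548 and 72.1 counts), mt-Cytb of -2.94 (478 and 64 counts), Calm1 of -2.67 (138 and 22 counts) and mt-Atp6 of -1.63. Nanog, a pluripotency factor, and Prr15 were counted almost only in replicate 1, with 110 and 1 and with 121 and 0 counts. Map1b lay at 0.18, Tubb5 at 0.75 and Tuba1a at -0.93. Of 26 genes with at least 100 summed counts, 17 were at least 2-fold apart after TMM scaling, 5 higher in replicate 2 and 12 higher in replicate 1. The 17 include rows that are not protein-coding or have no gene type, such as Gm28661, Gm28437, Gm42418 and ENSMUSG00000045999.9. How reads were split between such rows and others is uncertain. There is 1 library on each side, so these ratios have no replicate check and no p-value.

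Among 224 nuclear protein-coding genes of at least 20 summed counts, 42 had over 90% of their counts in replicate 1 and 11 in replicate 2. The leading ones were Prr15, Nanog, Rpl37a and the splicing factor gene Snrpb (77 and 0) in replicate 1, and Lars2, Usp25 (0 and 92.9), Eif4g2 (7 and 87) and Wdr34 (0 and 54) in replicate 2. Variance over the Poisson variance rose from 1.38 for genes of 2 to under 5 summed counts to 9.39 for 20 to under 50 and 48.9 for 50 or more, so that the libraries differed by more than sampling noise, which does not show that they are separate samples. Across 858 genes of at least 10 summed counts, Pearson's r of log2(TPM + 1) was -0.148 (bootstrap 95% interval -0.237 to -0.0551) and Spearman's rho -0.0196. Genes were chosen here on the sum of both libraries' counts, which favours genes high in either one, so that a negative r does not show that the libraries differ, and it turned positive, to 0.493, without the filter on low counts. Across all 21474 protein-coding genes the rho of the counts was 0.496. Both positive values include genes without a count in either library, as 8784 of 43346 mouse genes had one. Such genes raise the correlation, so these values do not measure agreement in level among counted genes. The common biological coefficient of variation from edgeR was 0.507 over the 83 genes that passed its filter. For a single group this filter asks for enough counts in both libraries, which genes such as Prr15, Nanog, Snrpb and Usp25 lack. The value of 0.507 therefore leaves out their disagreement. Without the filter it was 0.893 over 8698 genes. In the simulation at the files' depth the estimate without the filter was 0.519 for a set value of 0.4, so 0.893 may be too high.

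**Figure D2:**
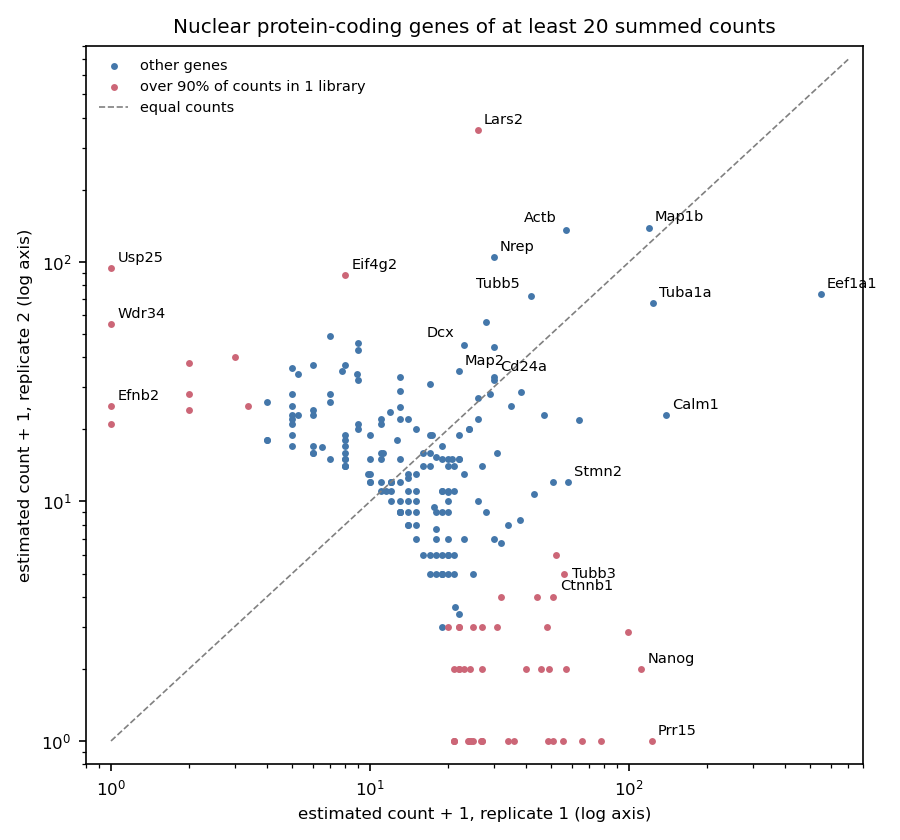
Estimated count + 1 of each nuclear protein-coding gene of at least 20 summed counts in replicate 1 (horizontal) against replicate 2 (vertical), both on log axes; points are genes, the dashed line marks equal counts, and red points have over 90% of their counts in 1 library. Map1b (118 and 138 counts) lies near the line, while Prr15 (121 and 0) and Usp25 (0 and 92.9) lie on the axes.

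The gene lists that could be compared between the libraries lay within the spread of random lists. Of the 4 lists with at least 5 members of at least 10 summed counts, 0 had a median log2 ratio outside the central 95% of expression-matched random lists. The radial glia median was 1.23 in favour of replicate 2 (5 members, 93.6th percentile), the pan-neuronal median 0.30 (8 members, 75.8th), the imprinted median 0.02 (8 members, 53.9th) and the mitochondrially encoded median -0.16 (11 members, 73.4th). In composition, mitochondrial genes took 12.2% of mouse counts in replicate 1 and 7.44% in replicate 2, and long intergenic noncoding RNAs 2.81% and 13.9%. Gm42418 alone had 328 and 2897 counts. The row ENSMUSG00000045999.9, which has no matched gene type and is outside that share, had 993 and 0. Both rows together had 1321 and 2897, so that the difference in the noncoding share is uncertain. Of Gm42418's windows of 36 bases, 95.8% lie in the reverse complement of a gene annotated as ribosomal RNA.

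Mitochondrially encoded messenger RNAs had 11 of 13 members at 1 TPM or more in both libraries. mt-Co1, a subunit of complex IV, had 384 and 507 counts, mt-Nd4, of complex I, had 194 and 163, and mt-Nd1 133 and 123, whereas mt-Co2 had 637 and 0.15 and mt-Nd4l 109 and 0. Nuclear pseudogene copies share reads with several of them, so that the split between gene and copy is uncertain: Gm28661, whose windows of read length all occur in mt-Co2, had 0 and 316 counts. Of the 9 RNAs listed as lacking a poly(A) tail, 3 were found in both libraries. These were the mitochondrial ribosomal RNAs mt-Rnr2 with 466 and 511 counts and mt-Rnr1 with 236 and 110, and Rn7sk with 2 and 1. The mitochondrial ribosomal RNAs thus held nearly all counts of this list. Whether they lack such a tail was not tested.

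Transcript usage was resolved for few genes. Among the fixed isoform genes, Dlg4 had the same top transcript in both libraries, ENSMUST00000143920.2, at 73.6% and 100% of the gene, as did Dnm1 with ENSMUST00000141633.1 at 100% and 75.5% and Clta with ENSMUST00000107845.3 at 100% in both. Pkm, the pyruvate kinase gene, had ENSMUST00000034834.11 at 100% in replicate 1 but both of its transcripts at 50% in replicate 2. Mapt, which encodes tau, and Ank3, an axon initial segment scaffold, had different top transcripts, at 32.8% and 100% and at 38.3% and 45.3%. Ptbp2 and App have 1 transcript each in the files. These genes had 2 to 18 counts per library. Of 2207 protein-coding genes with at least 5 TPM in both libraries and at least 2 transcripts, 1286 had a transcript of at least 80% in both and 735 had the same top transcript, which is 33.3% against 20.9% for even draws. A tie for the top transcript occurred in 8 of these genes, and 729 of the 2199 others had the same top transcript. Of the 2207 genes, 1933 had under 5 counts in a library. An even split between 2 transcripts was simulated at the files' counts over 2784 genes, without leaving out those with 1 transcript. It gave 29.4% of them such a dominant transcript. Each simulated read belonged to a single transcript, whereas the estimator splits shared reads. Of the 274 genes of at least 5 counts in both libraries, 79 (28.8%) had a dominant transcript, and 90 the same top transcript, 32.8% against 18.3% for even draws. The simulation gave 0.87% of 344 genes of at least 5 counts a dominant transcript. As it held no shared reads and other genes, this contrast does not show that a transcript dominates. With posterior mean TPM only 63 of 6303 genes had a dominant transcript, while 5326 had the same top transcript, so that both results depend on the estimate used. Among the 17 genes of at least 20 counts in both libraries, 4 had a dominant transcript and 3 the same top transcript, 17.6% against 17.3% for even draws.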

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

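All tests in this part were chosen after the data had been examined, and all except that on shared windows over all 53 genes after their own results were seen; its bootstrap interval was added later. Signal outside the mouse genes stood far above the 3 counts that a count of 0 allows on the phiX174 row, with 132216 counts in replicate 1 and 127388 in replicate 2, and on the 26248 rows whose identifier is a number, with 48 and 62 counts, of which 0 rows had a count in both libraries.

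Mouse genes thus received few counts beside phiX174. A shortage of mouse reads among the alignments stays open: the sizes listed for the tracks of uniquely aligned reads, 67.6 and 73.2 megabytes, come to 2670 and 3030 bytes per counted mouse read, but the bytes a read takes in a track were not measured. Counting on the strand opposite to the transcripts, possible only with a stranded kit, also stays open: genes that overlap exons of the other strand are 24.3% of nuclear protein-coding genes and held 28.9% of their counts in replicate 1 and 28.6% in replicate 2, between the bounds set for either outcome. The design holds a single group, so no biological explanation was tested.

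Of 224 nuclear protein-coding genes with at least 20 summed counts, 53 had over 90% of them in a single library. Counting noise is argued against, since binomial sampling of the same counts would put 0.0417 genes there. For 10 genes, among them Prr15, Usp25, Ctnnb1 and Efnb2, no 36-base window occurred in another annotated gene. This argues against reads shared exactly with another M21 transcript in the same orientation. Copies with a mismatch, on the other strand or only in M4 were not searched, so sharing with these stays open for the 10 genes too. Shared reads stay open for the others. Before the result was seen, a median over 50% of windows shared was set for sharing and a median under 10% against it. The median over all 53 genes was 8.48%, under the lower bound. Its bootstrap 95% interval, added later, was 2.28 to 22.2 and reached past 10%, so that the bounds do not decide. Over the 171 other genes of at least 20 counts the median was 0.599%, a contrast that goes with sharing. Of the 53 genes, 7 shared over 50%, against 8 of the 171 (Fisher's exact test, two-sided, p = 0.0526). Repeated copying of few molecules cannot be told apart from differences between the samples, since both would raise the variance over its Poisson value, which was 48.9 among 39 genes of at least 50 counts. No biological explanation was tested.

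Some mitochondrial genes and their nuclear copies were counted in opposite libraries. Gm28661 on chromosome 1 (24614885 to 24615565) had 0 and 316 counts where mt-Co2 had 637 and 0.15, and Gm28437 had 621 and 0.02 where mt-Co3 had 0.50 and 23.0. A split of shared reads between identical copies is a candidate explanation: over 5 such copies the smallest share of a copy's windows found in its mitochondrial gene was 97.2%. Summed over gene and copy, mt-Nd4 had 230 and 215 counts and mt-Co1 423 and 507, about level between the libraries, whereas mt-Co2 had 637 and 317, mt-Co3 621 and 23 and mt-Nd3 5 and 42, so that for these the split leaves a difference. No biological explanation was tested.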

How the results depend on the processing

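The alternatives of at least 3 counts, at least 1 count and at least 20 counts in both libraries, of TPM rescaled to mouse genes, and of genes without a tie for the top transcript, were chosen after the results were seen. With posterior mean TPM, in which genes without a read have values above 0, detected genes rose from 3435 to 32838, list members from 115 to 268 and pairs with the early partner higher from 2 to 5, while genes with a dominant transcript fell to 63 and genes with the same top transcript came to 5326 of 6303. At least 3 counts in both libraries left 872 genes and 57 list members. Each library alone gave 6077 to 6137 detected genes, 161 to 167 list members, 4 to 7 pairs and 3075 to 3091 genes with a dominant transcript. The correlation between the libraries, -0.148, reversed to 0.493 without the filter on low counts, which lets in genes without a count in either library. It was 0.439 over the 730 genes that passed this filter and also had at least 1 count in both libraries, and -0.304 at 100 summed counts. The cause was not tested. The biological coefficient of variation was 0.893 without the filter, a setting in which the simulated value of 0.4 was also estimated high, at 0.519. Genes 2-fold apart numbered 515 of 858 at 10 summed counts and 1 of 1 at 1000. At 20 TPM 388 of 924 genes had a dominant transcript and 279 the same top transcript, and at 20 counts in both libraries 4 and 3 of 17, fewer genes being tested. With a pseudocount of 0.1 that correlation was -0.224, inside its bootstrap interval. On CPM the early partner was higher in 2 pairs as well, but with Scn3a in place of Eno1. All other alternatives kept each result within 1.5 times its value or, for the Hox correlation, at a permutation p of 0.145 to 0.798. By list, 39 of 39 stayed so at 0.5 TPM, at 1 CPM and with rescaled TPM, 34 at 5 TPM, 24 and 25 with each library alone, 18 at 3 counts and 8 with posterior means. At 0.5 TPM, at 1 CPM and with rescaled TPM nearly any count passes, as at 1 TPM (3435 genes, against 3438 with a count above 0 in both libraries). Those settings could hardly change the number of detected genes or list members and do not show that it is stable. The Hox alternative of at least 10 summed counts left 0 genes and was not run. Depth limits most of these results, as 340 and 299 genes reached 10 counts.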

Other observations

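The genes named in this part were chosen after their values were seen. Gm42418, a long intergenic noncoding RNA gene on chromosome 17 (39846958 to 39848788, GRCm38), had 328 counts in replicate 1 and 2897 in replicate 2, the most of any mouse gene over both libraries. It lies opposite to a gene annotated as ribosomal RNA, whose reverse complement holds 1720 of its 1796 windows of 36 bases. The row ENSMUSG00000045999.9, without a matched symbol, had 993 and 0 counts, so that both rows together had 1321 and 2897. Gapdh, a glycolytic enzyme used by every cell, was listed at 0 in both libraries. By counting error alone this allows up to 119 CPM of the mouse counts in replicate 1 and 124 CPM in replicate 2. Whether its reads were assigned to other rows was not tested, so the 0 does not show that its RNA was absent.

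Among genes of growing neurites some had similar counts in both libraries and others did not. Crmp1, a semaphorin signalling protein, had 23 and 19 counts (164 TPM ± 10.4, SD, n = 2), the neurite outgrowth inhibitor gene Rtn4 had 23 and 19 (128 TPM ± 22.1), and the motor protein gene Kif1b had 16 and 15 (46.2 TPM ± 1.73). The intermediate filament gene Ina had 16 and 30, Dpysl3 8 and 45 and the microtubule regulator Stmn1 2 and 39. Among genes of RNA-binding proteins, Hnrnpa0 had 21 and 18 counts and Hnrnpa3 16 and 18, whereas Hnrnpa1 had 4.29 and 32.9, Hnrnpab 8 and 20 and Hnrnpk 12.1 and 23.8.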
